A study of Homo sapiens with 4 samples.

How the data were processed

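H3K27ac chromatin immunoprecipitation was performed on human primary melanocytes 72 h after transfection with control siRNA or MITF siRNA. Per the labels' protocols, cells were fixed in formaldehyde, chromatin was sheared to 200 to 500 bp, and 15 µg of chromatin was incubated with 5 µg of antibody. Each condition has 1 immunoprecipitated library and 1 input library. Groups were taken from the sample labels.

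The deposited files are 2 broad peak lists, 1 per H3K27ac library. The submitters' processing notes name MACS2 and the hg19 genome build. The aligner, the MACS2 version, the peak calling settings and the role of the input libraries are not given in the sources used here. Peak names in the deposited lists show that duplicate reads were removed and that each list comes from 1 library, so nothing was pooled. They also show different sequencing pools and flow cells for the conditions. The authors' score column is 10 times the -log10 q cut to a whole number, except in 3 peaks of each list. The authors' fold enrichment is the ratio of the peak over the caller's background. The deposited -log10 p and -log10 q values belong to each peak, with a lowest -log10 q of 1.00 in the control list and 1.02 in the MITF siRNA list. These values describe, rank or filter peaks within their own list, and are the authors' own. The lists give no read totals, so depth per library is unknown, and a list from a deeper library holds more and wider peaks for the same chromatin.

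From the lists, peaks on chromosomes 1 to 22 and X were used, which left out 176 of 61163 control peaks and 102 of 47812 MITF siRNA peaks. Overlap meant at least 1 shared bp, with exact (Clopper-Pearson) 95% intervals. The Jaccard index was set beside 100 circular shifts of 1 list along each chromosome. Peaks within 12.5 kb were joined into domains in each list, and into regions over both lists. A region was a loss where the MITF siRNA list covered at most 50% of the control length and at least 5 kb less, and a gain by the mirror rule. Coordinates are hg19, counted from 1.

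No hg19 gene annotation or genome was used here, and for that case the design fixed before the data were examined left gene lists out. This was not followed. For 237 of the 239 genes on lists fixed before the data were examined, hg19 gene spans were instead entered by hand from general knowledge. Spans were kept where the chromosome matched and the length was within 15% of the gene's length in a GRCh38.p14 gene table, which left 209 genes. No coordinate of that table is printed. Gene order along the chromosomes was the same as in the table for 209 of 209 neighbouring pairs among all 232 kept spans. The shift between builds at a gene's start and end differed by a median of 51.5 bp and by over 5 kb for 7 genes. That difference equals the difference in gene length, so it repeats the length check and does not test position. A span of the right length that is misplaced without a change of gene order would pass all of these checks. The spans came in stages. The first 75 (71 kept) were entered before any locus value was seen. Another 162, which completed the lists, were entered after list results from the first had been seen. A further 25 (23 kept), used only to name regions, were entered after those regions had been seen. Only names attached at these stages are given, so a region without a name can still hold a gene.

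A locus was a gene span with 20 kb on either side. Its log2 ratio was taken of covered length after MITF siRNA over control, with 1000 bp added to both, which understates differences at loci with little coverage. Each locus was ranked among up to 1000 windows of the same width, drawn around peaks from a pool of 100000, whose mean covered length was within 20% of its own, and at least 100 such windows were required. The pool was enlarged after a first run had left wide loci with too few windows. These windows replaced the planned matching on other genes, which needs a genome-wide annotation. A list's median was ranked among 10000 random lists drawn from the windows of its members. Windows were drawn separately for each member, so where members of a list share peaks the spread of its random lists is too narrow. Percentiles describe these libraries and are no test of the siRNA. The lists were pigmentation, melanocyte lineage, other MITF targets, lysosome, MITF-low state, cell cycle, checkpoint and antigen presentation, interferon response, p53 and UV response, housekeeping, and markers of keratinocytes, fibroblasts, and endothelial and blood cells.

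In the design fixed before the data were examined, regions by coordinates were to be named without an hg19 annotation, and genes and list members with one. The rule used here combined both, and this combination was not fixed beforehand. It takes MITF, CD274 and PDCD1LG2, the 10 regions with the largest loss and the 10 with the largest gain of covered length, the 2 members of each list with the largest loss and the 2 with the largest gain, list members that meet the loss or gain rule where these are 6 or fewer, and the 20 widest control domains. JAK2, MLANA and the few other genes named outside it were chosen after their values were seen. Some genes that the rule takes are not reported here.

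The locus ranking was tested on simulated lists made by thinning the control list. Of 50 windows with 80% of peaks removed, 82.0% fell below the 2.5th percentile, as did 2.67% of 150 windows without planted loss. Above the 97.5th percentile lay 0.667% of those 150. The simulated list held only unchanged peaks of the control list, and its windows lay around wide control peaks. The MITF siRNA list has 8424 peaks without a control counterpart, so these rates need not hold for it or for loci with little coverage. The gain rule was not tested in this way. Alternatives covered stricter -log10 q limits, equal covered length, peak width, joining of peaks, chromosomes, the overlap rule, promoter and locus windows, the added length, the size rule and the joining distance. For equal covered length, each list was cut to its peaks of highest -log10 p, up to 80% of the shorter list's covered length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.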

Results

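H3K27ac, a histone mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in human primary melanocytes, the pigment-producing cells of the skin. Cells were collected 72 h after transfection with a control siRNA or with an siRNA against MITF, the transcription factor that directs melanocyte identity and pigment production. The series holds 4 samples, 1 H3K27ac library and 1 input library per siRNA. The comparison here is between the 2 deposited H3K27ac peak lists, 1 per condition, and the input libraries were not analysed here. The series asks how MITF governs PD-L1, the immune checkpoint ligand encoded by CD274. With 1 library per condition no difference below has a replicate check and no test between conditions was made. The libraries were also sequenced in separate runs, so run and siRNA cannot be told apart. Read depth is unknown from the files. At equal fold enrichment the control list had the higher -log10 p, so a deeper control library stays open for every loss below. Intervals given for shares cover counting error only. Gene positions in hg19 were entered by hand from general knowledge, in stages, against the design fixed beforehand, and every value at a gene rests on them.

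The MITF locus carried the widest H3K27ac domain of control cells, and it kept most of its listed H3K27ac after MITF siRNA. Peaks joined across short gaps formed a domain of 272 kb on chromosome 3, from 69760580 to 70032159 (hg19). Over the gene with 20 kb on either side, peaks covered 141 kb in control cells and 123 kb after MITF siRNA, in 19 and 18 peaks. The ratio of 0.868 lay at the 54.8th percentile among 263 windows of the same width and similar covered length elsewhere in the genome. An siRNA acts on the transcript and not on the gene's chromatin, so this value does not check the knockdown, and MITF transcript or protein levels were not analysed here.

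CD274 and its neighbour PDCD1LG2, which encodes the related ligand PD-L2, had less listed H3K27ac after MITF siRNA. At CD274 with 20 kb on either side, covered length was 5.66 kb in 3 peaks in control cells and 1.80 kb in 1 peak after MITF siRNA. A control peak over the 5′ end of CD274 (chromosome 9, 5450041 to 5451422, hg19) and an upstream control peak (5443008 to 5444798) had no counterpart in the MITF siRNA list. The 5′ peak was weak in its own list, with a fold enrichment of 2.65 and 80.5% of control peaks above it by -log10 q, and 68.4% of control peaks in its decile lacked a counterpart. The peak at 5443008 was stronger, with a fold enrichment of 10.6, in a decile where 7.26% lacked a counterpart. The upstream peak at 5436840 to 5439329 did have a counterpart, at 5436994 to 5438792. At PDCD1LG2, covered length was 10.5 kb in 7 peaks in control cells and 2.07 kb in 2 peaks after MITF siRNA. The peak just beyond the gene at 5581757 to 5584765 had a fold enrichment of 15.6 in the control list, where 0.467% of peaks had a higher -log10 q. The MITF siRNA peak that overlapped it, at 5582442 to 5583766, was 1325 bp wide against 3009 bp. In its own list that peak had a fold enrichment of 4.14 and 55.0% of peaks above it by -log10 q, and ranks or folds from lists of different length show no change by themselves. Among windows matched in width and covered length, CD274 lay at percentile 10.1 of the ratio and PDCD1LG2 at percentile 1.80. The CD274 value is therefore within the middle 95% of such windows. On the same arm, JAK2 (4.68 kb in control cells and 2.82 kb after MITF siRNA) and MLANA (31.5 kb and 27.1 kb) differed less. They do not stand for the arm. There, BNC2 had 135 kb and 72.8 kb (7.4th percentile) and the region from 27460540 to 27499806 had 13.3 kb and 1.39 kb. DDX58, with 0.491 kb and 1.81 kb, went the other way.

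**Figure D1:**
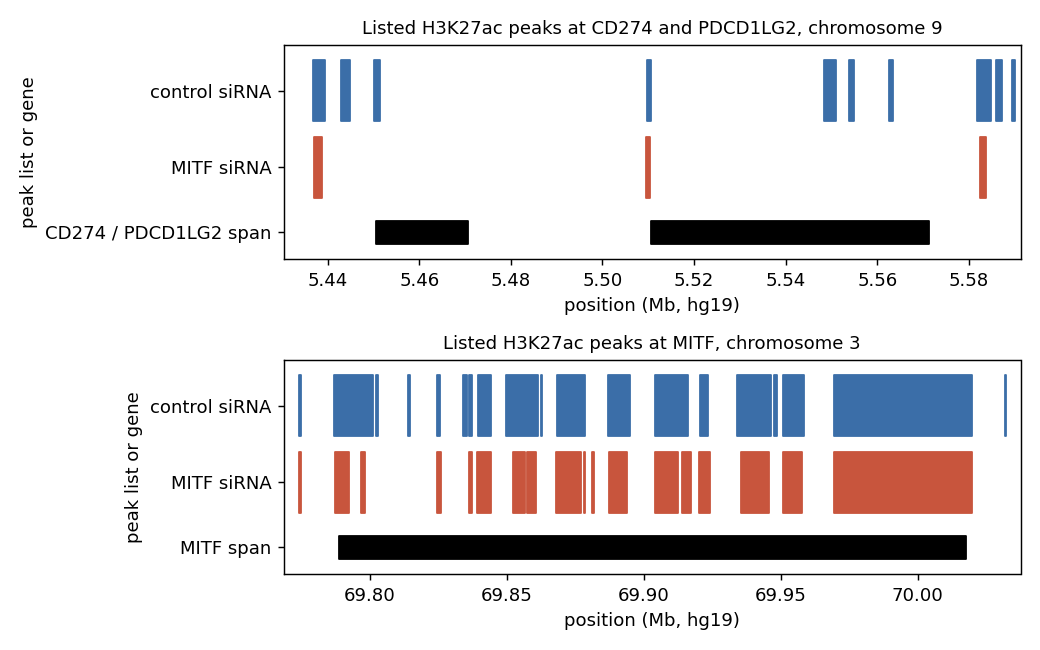
Listed H3K27ac peaks (boxes) in control siRNA and MITF siRNA melanocytes along hg19 positions in Mb, with black bars for the gene spans. Within 20 kb of the gene span the lists hold 3 and 1 peaks at CD274, 7 and 2 at PDCD1LG2, and 19 and 18 at MITF, and on the span itself 1 and 0, 4 and 0, and 17 and 17.

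Genes of the lysosome, the degradative organelle whose genes MITF and its relatives TFEB and TFE3 regulate, had less listed H3K27ac after MITF siRNA at 17 of 21 loci with peaks. Over all lists, 140 of 192 loci with a percentile were lower and 52 higher, so a majority of lower loci is not particular to a single list. CTSB, encoding the protease cathepsin B, had 6.01 kb after MITF siRNA, 0.287 of its control length. SQSTM1, an autophagy receptor, had 20.3 kb and 7.61 kb, and the lysosomal calcium channel gene MCOLN1 had 13.4 kb and 4.57 kb. HEXA (4.37 kb after MITF siRNA, 0.382 of its control length) and TFEB (9.90 kb and 3.84 kb) also met the loss rule for size. The largest gains were ASAH1, at 9.50 kb in control cells and 10.9 kb after MITF siRNA, and ATP6V0D2, with no control peak and 0.949 kb after MITF siRNA. The median log2 ratio of the list was -0.61, at the 4.59th percentile of 10000 random lists of matched windows, which is inside the middle 95%. With both lists cut to equal covered length, CTSB no longer stood below its matched windows (relative log2 ratio 0.12 against -1.29). This list had no ranked locus among the gene positions entered first.

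Pigmentation genes had less covered length after MITF siRNA at all 15 loci with peaks, where 140 of 192 loci over all lists were lower. OCA2, a melanosome membrane protein gene, had 86.9 kb in control cells and 39.4 kb after MITF siRNA, at the 3.90th percentile of its matched windows. TRPM1, a melanocyte ion channel gene, had 119 kb and 83.7 kb. The median log2 ratio of the list was -0.43, at the 24.5th percentile of random lists and -0.074 relative to their median. This relative value was below 0 in each of 10 alternatives and reached -0.32 with -log10 q of at least 10. Other MITF target genes were lower at 13 of 16 loci, with a list median of -0.55 at the 7.75th percentile. Their largest differences were at MET, a receptor tyrosine kinase gene with 118 kb in control cells and 66.0 kb after MITF siRNA (1.36th percentile), and at BCL2, an anti-apoptotic gene with 85.6 kb and 52.6 kb. The DNA ligase gene LIG1 had 17.1 kb and 4.96 kb, BCL2A1 had 20.2 kb and 8.03 kb, and HIF1A had 9.76 kb and 2.96 kb. TBX2, at 6.51 kb in control cells and 9.47 kb after MITF siRNA, and CDKN2A, at 8.55 kb and 9.55 kb, went the other way. With only the gene positions entered first, this list held 9 loci and its percentile was 62.2.

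Genes of the MITF-low state, an invasive and mesenchymal-like expression program known from melanoma cells, had more listed H3K27ac after MITF siRNA at 11 of 18 loci with peaks. NRP1, a semaphorin and VEGF co-receptor gene, had 2.18 kb in control cells and 7.23 kb after MITF siRNA. CDH2, encoding N-cadherin, had 5.39 kb and 10.6 kb. TEAD1, at 48.1 kb and 37.9 kb, had the largest loss of the list. In all, 7 loci were lower. They included AXL (5.69 kb and 5.61 kb), NGFR (2.15 kb and 1.57 kb), EGFR (2.165 kb and 1.063 kb) and CTGF (1.485 kb and 0.933 kb). The median log2 ratio of the list was 0.31 where matched random lists had -0.34, at the 99.98th percentile. With only the gene positions entered first, 10 loci with peaks remained, of which 6 were lower and 4 higher, with a median log2 ratio of -0.057 at the 85.9th percentile. On those positions the direction of the list's own median thus turned round. The fibroblast marker list stood at the 91.8th percentile, and its 9 loci with peaks covered 11.4 kb in control cells and 12.1 kb after MITF siRNA. Its median relative to random lists was 0.50 and turned to -0.34 at equal covered length. COL3A1 had no control peak and 1.22 kb after MITF siRNA, FBLN1 had none and 0.688 kb, whereas COL1A1 had 3.87 kb and 2.52 kb and PDGFRA 1.54 kb and 0.896 kb.

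Lineage genes of the melanocyte lost less listed H3K27ac than matched windows. They were lower at 9 of 15 loci and higher at 6, with a median log2 ratio of -0.059 where random lists had -0.30, at the 99.3rd percentile. MCAM, a cell adhesion gene, had 10.4 kb in control cells and 15.5 kb after MITF siRNA, and ZEB2, a transcription factor gene, had 71.4 kb and 77.4 kb. KIT, a receptor of melanocyte growth and survival, had 88.1 kb in 6 peaks and 62.7 kb in 19 peaks. Its widest peak was 64994 bp in control cells and 13876 bp after MITF siRNA. Fewer bases in more and narrower peaks do not by themselves show loss of the mark. IRF4, a pigmentation-related transcription factor gene, had 17.5 kb and 8.58 kb. With the gene positions entered first, the list held 7 loci and stood at the 76.2nd percentile.

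The remaining lists stayed within the middle 95% of random lists. Checkpoint and antigen presentation genes were lower at 16 of 20 loci (16.9th percentile). Their median relative to random lists was -0.16, and it turned to 0.12 with -log10 q of at least 5 and went to -0.68 with at least 10. Members with large differences were CD276 at 11.9 kb in control cells and 6.12 kb after MITF siRNA, PVR at 1.06 kb and 2.17 kb, and B2M at 9.57 kb and 10.7 kb. Reads of the HLA genes can be shared between paralogs, and TAP1, TAP2, PSMB8 and PSMB9 share 1 domain. In the interferon response list, IFIT2 and IFIT3 share their widest peak. PMEL of the pigmentation list and CDK2 of the other MITF targets also share theirs. Interferon response genes stood at the 82.1st percentile (26.9 with the 3 gene positions entered first), with IRF2 at 14.3 kb and 8.52 kb, ISG15 at 6.87 kb and 9.22 kb, and IRF1 at 2.92 kb and 4.52 kb. Genes of the p53 and UV response stood at the 92.3rd percentile, with a median log2 ratio of 0.24 relative to random lists that turned to -0.50 with the 3 entered first. The whole list included BBC3 at 8.01 kb after MITF siRNA, 0.472 of its control length, SESN1 at 14.4 kb and 7.38 kb, ATF3 at 6.85 kb and 9.37 kb, and XPC at 8.38 kb and 9.28 kb. Cell cycle genes stood at the 69.9th percentile. Their relative median of 0.081 kept its sign in 5 of 9 alternatives and reached -0.30 with -log10 q of at least 10. The list held MCM2 at 11.9 kb and 5.28 kb, AURKB at 19.1 kb and 13.4 kb, AURKA at 20.6 kb after MITF siRNA, 1.29 times its control length, and CCNE1 at 4.13 kb and 5.15 kb. Housekeeping genes were lower at 11 of 12 loci and stood at the 35.8th percentile, with TUBB at 18.3 kb and 13.1 kb and YWHAZ at 12.6 kb and 14.3 kb. Keratinocyte markers (56.1st percentile) were ranked at 8 loci. Among them were KRT10 with 4.72 kb and 3.32 kb, COL17A1 with 0.938 kb and no peak, and KRT14 and KRT17, which share 1 peak of 0.771 kb listed after MITF siRNA. Endothelial and blood markers (83.5th percentile, or 41.7 with the 4 entered first) were ranked at 8 loci, with VWF at 5.27 kb and 3.44 kb, SPI1 at 1.85 kb and 0.426 kb, KDR at 0.475 kb and 1.52 kb, and TEK at 3.60 kb and 4.26 kb. Of all 192 listed loci with a percentile, 3 lay below 2.5 (PDCD1LG2, MET and CTSB) and 3 in the highest 2.5% (CYR61, THBS1 and NRP1), where 4.80 on each side follow from the definition. CYR61 and THBS1, named after their values were seen, are in the MITF-low list and had 1.14 kb and no peak in control cells against 4.42 kb and 1.83 kb after MITF siRNA.

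**Figure D2:**
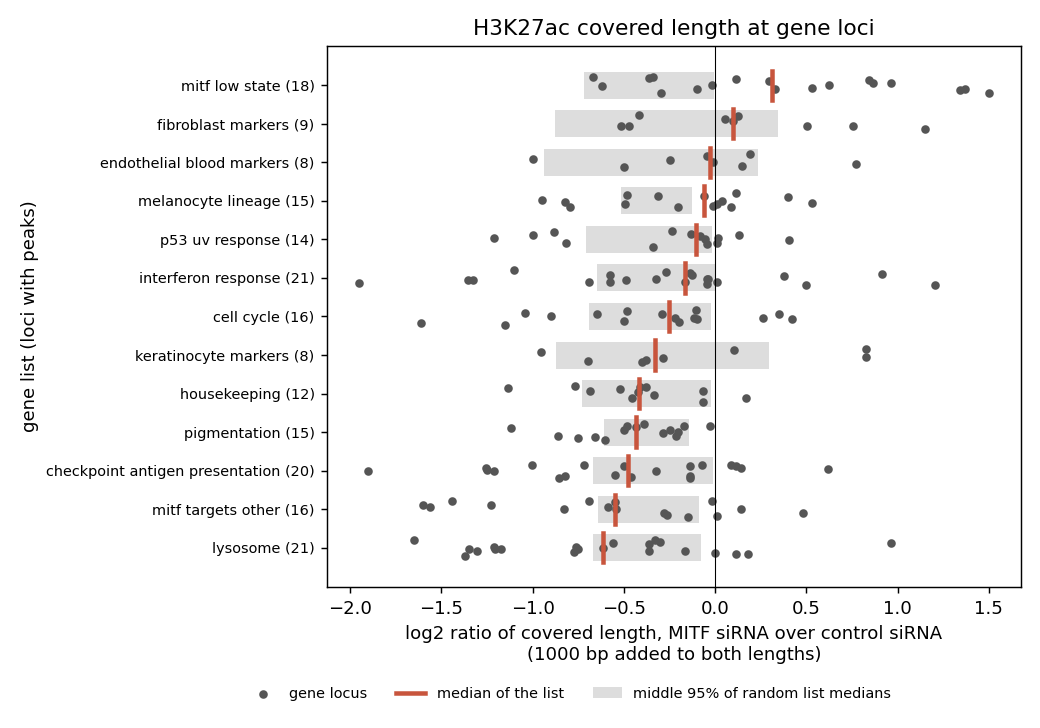
Each point is the log2 ratio of H3K27ac covered length at 1 gene locus, MITF siRNA over control siRNA, with red bars for list medians and grey bands for the middle 95% of medians of random lists of matched windows. The MITF-low list (median 0.31) and the melanocyte lineage list (median -0.059) lie above their bands.

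A peak within 2 kb of the hand-entered 5′ end was present in both lists at 141 of 209 genes, in the control list alone at 13, in the MITF siRNA list alone at 4 and in neither at 51. Of the genes with such a peak in control cells alone, 5 were cell cycle genes (AURKB, CCNB1, CDK1, E2F1 and MCM2) and CD274, with its weak control peak of fold enrichment 2.65, was another. THBS1, a matrix protein gene of the MITF-low list, had one after MITF siRNA alone. These names were taken after the values were seen. Only 1 hand-entered 5′ end per gene was used, so a peak at another start site of the gene is missed. TRPM1, with 119 kb and 83.7 kb at its locus, and EDNRB, with 44.7 kb and 31.4 kb, counted as having no such peak in either list. The counts thus depend on the end chosen. The balance turned round when both lists were cut to equal covered length, with 4 genes in the control list alone and 22 in the MITF siRNA list alone. That cut left 18906 control and 27677 MITF siRNA peaks, and these unequal numbers enter into the balance.

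Regions were ranked by the difference in covered length, a ranking that favours broad domains. The loss of listed H3K27ac was not confined to the regions named here, since 44.8 Mb of control coverage was absent from the MITF siRNA list. On chromosome 16, the region from 48269951 to 48428292, which overlaps LONP2, had 102 kb covered in control cells and 34.8 kb after MITF siRNA. A region at CFAP61 on chromosome 20 (20032112 to 20218477) had 112 kb and 48.0 kb, and one at ADAM10, a sheddase gene, on chromosome 15 (58876669 to 58998981) had 81.1 kb and 27.1 kb. Regions at MET, ST3GAL1, CDH1, DLGAP1 and OCA2 and regions starting at 63011715 on chromosome 10 and 117243375 on chromosome 9 complete the 10 with the largest loss. At the CDH1 locus, peaks went from 10 in control cells to 13 after MITF siRNA, and the widest from 73457 bp to 13696 bp. Such a change to more and narrower peaks does not by itself show loss of the mark. The longest gain was on chromosome 9 from 15826415 to 16107435, with 130 kb in control cells and 178 kb after MITF siRNA. This was also the widest domain of the MITF siRNA list, at 281 kb. Regions at C10orf90 (60.0 kb and 90.7 kb), STARD13 (27.8 kb and 55.1 kb), RCAN1 (23.9 kb and 44.6 kb) and CRADD (41.1 kb and 60.6 kb) followed. NFATC2, a calcium-regulated transcription factor gene, had 8.96 kb and 25.5 kb in its region, PDZRN3 had 2.85 kb and 17.6 kb, and AFAP1L2 had 1.61 kb and 15.4 kb. VEPH1 (22.1 kb and 35.6 kb) and a region on chromosome 8 from 41004353 (4.64 kb and 17.7 kb) were the last of the 10. Apart from MET and OCA2, which are in the fixed lists, gene names of these regions were attached after the regions were seen.

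Over 37584 regions joined from both lists, 784 had at most 50% of the control covered length and at least 5 kb less after MITF siRNA, and 84 met the mirror rule for gain, so that 90.3% of such regions were losses. After lengths were scaled to the same total, 373 regions met the loss rule and 340 the gain rule, 52.3% losses. All 20 of the widest control domains were less covered after MITF siRNA, with ratios from 0.340 to 0.954 and a median of 0.764. Besides MITF they included domains at JARID2, HDAC4, BNC2, CFAP61, INPP4B, SPTBN1, FMN1, LONP2, PTPRJ, TRPM1 and CDH1. Of the 20 widest MITF siRNA domains, 16 were more covered in control cells and 4 less, and 5 overlapped a domain among the widest 20 of control cells.

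The MITF siRNA list was shorter in total. It held 47710 peaks covering 82.1 Mb, and the control list held 60987 peaks covering 110.2 Mb. Mean width was 1721 bp in the MITF siRNA list and 1807 bp in the control list, while the median went the other way, at 1224 bp and 1174 bp. Within each list the mean and median fold enrichment were 5.28 and 4.45 after MITF siRNA and 5.36 and 4.23 in control cells. The ratio of covered length was 0.745 overall and ranged from 0.668 on chromosome 16 to 0.828 on chromosome 21. Of control peaks, 62.3% (61.9 to 62.7, exact 95% interval) overlapped an MITF siRNA peak, and 82.3% (82.0 to 82.7) of MITF siRNA peaks overlapped a control peak. The Jaccard index of covered bases was 0.516, where lists shifted along the chromosomes gave 0.016 on average. Among the strongest 10% of peaks by their own -log10 q, 97.2% of control peaks and 98.5% of MITF siRNA peaks were shared, and among the weakest 10%, 25.8% and 64.0%. At equal covered length the order of the overall shares turned round, to 78.5% of control peaks and 55.0% of MITF siRNA peaks. That cut left 18906 control and 27677 MITF siRNA peaks, and these unequal numbers enter into the shares.

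**Figure D3:**
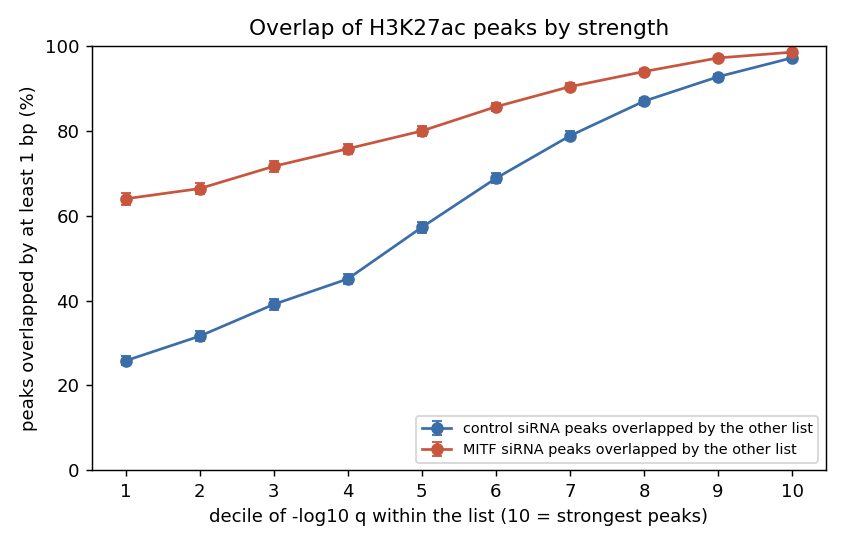
Percent of H3K27ac peaks overlapped by at least 1 bp in the other list, by decile of -log10 q within the list, with exact 95% intervals for counting error. Control siRNA peaks go from 25.8% in the weakest decile to 97.2% in the strongest, and MITF siRNA peaks from 64.0% to 98.5%.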

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

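The equal covered length, stricter -log10 q and other settings were chosen before the data were examined, except the percentile limits of 5 and 95 and the use of only the gene spans entered first. Over all alternatives 177 of 258 values of summary results stayed within their spread or within 1.5 times their count, as did 1570 of 1729 values of single loci and regions. Relative to the median of random lists, the MITF-low list stayed above 0 and the lysosome list below 0 in each alternative that gave a value (0.25 to 1.29, and -0.64 to -0.24). These are directions only. With the spans entered first, the MITF-low list was at the 85.9th percentile, inside the middle 95%, and the lysosome list had no value. CD274 (-2.13 to -0.52) and PDCD1LG2 (-2.78 to -0.86) stayed below the median of their matched windows in all 9. The causes of the moves below were not tested. Genome-wide promoter and gene domain counts and the E-box motif count were not run, for want of an hg19 annotation and sequence used here, and MITF had no value at -log10 q of at least 10 or at equal covered length, where under 100 windows matched. Depth limits all of this, since a deeper list is longer.

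With -log10 q of at least 5, the lists held 35027 control and 22614 MITF siRNA peaks, the covered length ratio was 0.653, the Jaccard index 0.466 and the overlaps 53.4% of control and 83.4% of MITF siRNA peaks, with 1271 loss regions. List medians relative to matched windows (log2) were -0.31 for pigmentation, 0.37 for melanocyte lineage, -0.40 for other MITF targets, -0.48 for lysosome, -0.17 for cell cycle, 0.12 for checkpoint and antigen presentation and 0.51 for keratinocyte markers. PDCD1LG2 was at -2.78.

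With -log10 q of at least 10, there were 23675 control and 12425 MITF siRNA peaks, a ratio of 0.539, a Jaccard index of 0.387, an overlap of 43.3% of control peaks and 1683 loss regions. Medians were -0.32 for pigmentation, -0.64 for lysosome, 1.29 for the MITF-low list, -0.30 for cell cycle, -0.68 for checkpoint and antigen presentation, 0.36 for interferon response, -0.086 for p53 and UV response, 0.87 for fibroblast markers and -0.28 for housekeeping. CD274 was at -2.13, 6 loci lay in the lowest 2.5% of their matched windows and 1 in the highest 2.5%, and 31 genes had a promoter peak in the control list alone.

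At equal covered length, 18906 control and 27677 MITF siRNA peaks remained, the Jaccard index was 0.475, the overlaps were 78.5% of control and 55.0% of MITF siRNA peaks, and 341 regions were gains. Medians were -0.19 for pigmentation, 1.14 for the MITF-low list, -0.22 for cell cycle, -0.039 for interferon response, 0.061 for p53 and UV response, -0.34 for fibroblast markers and -0.13 for endothelial and blood markers. CTSB changed sign, to 0.12, 0 loci lay in the highest 2.5%, and promoter peaks were in the control list alone at 4 genes and in the MITF siRNA list alone at 22.

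With peaks of at least 1 kb, there were 35514 control and 29127 MITF siRNA peaks, a Jaccard index of 0.509, overlaps of 63.4% and 79.3%, and a fibroblast marker median of 0.0064. Joining peaks within 1 kb gave an overlap of 62.8% of control peaks. On autosomes the melanocyte lineage median was 0.10. An overlap of at least 50% of the peak left 50.9% of control and 75.5% of MITF siRNA peaks shared, and a reciprocal one 44.3% and 56.6%. Spans extended by 5 kb gave medians of -0.35 for other MITF targets and -0.15 for interferon response, with 6 loci below the 2.5th percentile. Spans extended by 50 kb gave -0.36 for other MITF targets, 1 locus below and 1 above the limits. Adding 200 bp put the lysosome median at -0.41. Scaled to the same total, 373 regions were losses and 340 gains, and a minimum of 2 kb gave 3320 and 784.

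Among alternatives added after the data were seen, limits at the 5th and 95th percentile gave 9 loci below and 6 above. The spans entered first gave medians of 0.065 for melanocyte lineage, 0.049 for other MITF targets, 0.25 for the MITF-low list, -0.27 for interferon response, -0.50 for p53 and UV response and -0.080 for endothelial and blood markers.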

Other observations

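Peaks with no counterpart at all existed among the strong peaks of both lists. The strongest control peak without an MITF siRNA peak lay on chromosome 20 from 46309947 to 46312440, with a fold enrichment of 21.8 and rank 117 of its list by -log10 q. The strongest MITF siRNA peak without a control peak lay on chromosome 7 from 107585767 to 107591251, with a fold enrichment of 15.1 and rank 170. Outside the fixed lists, OSTM1, a gene needed for osteoclast and melanocyte lysosomes whose span was entered after its region had been seen, had 34.1 kb in control cells and 6.11 kb after MITF siRNA.

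All tests in the following paragraphs were chosen after related values had been seen.

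Fewer peaks were listed after MITF siRNA. Among control peaks with a fold enrichment of at least 7.8, 6.04% (649 of 10747) had no MITF siRNA peak, against 2.15% (145 of 6730) the other way. MITF siRNA peaks of fold 7.8 to 8.2 had a -log10 p of at least 13.7, and the lowest in that list was 2.68. These shares cannot tell whether depth alone removed strong control peaks. Control peaks were looked up in the shorter list, and strong peaks were not compared at equal covered length. Folds also differ between the lists, with a highest fold at MLANA of 16.2 in control cells and 9.91 after MITF siRNA. For the weaker peaks a deeper control library stays open, since at fold 4.9 to 5.1 the median -log10 p was higher by 3.47 in the control list, and higher in each of the 4 fold ranges compared. Weaker enrichment in the MITF siRNA immunoprecipitation could also remove strong peaks and was not tested. The sequencing run cannot be told apart from the siRNA, because the libraries shared 0 pools or flow cells.

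More H3K27ac was listed after MITF siRNA at 11 of 18 loci of the MITF-low list. With only the gene positions entered first, 6 of 10 loci were lower and the median log2 ratio was -0.057. THBS1, FN1, TNC and CYR61 of the MITF-low list are also expressed by fibroblasts, so fibroblasts in the MITF siRNA culture stay open as a possible explanation. Their marker list stood at the 91.8th percentile, with COL3A1 and COL1A2 (3.34 kb and 3.73 kb) higher, COL1A1 lower, LUM with 0.430 kb in control cells and no peak after MITF siRNA, and DCN without a peak in either list. The fibroblast list turned to -0.34 at equal covered length, where the MITF-low list was at 1.14. A shift of melanocytes toward the MITF-low state is a hypothesis that these libraries cannot separate from the run.

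Less H3K27ac was listed at CD274 and PDCD1LG2. A loss as large over the whole surrounding segment is excluded by the flanks, where the covered length ratio within 1 Mb on either side was 0.658 and over the segment from CD274 to PDCD1LG2 0.240, but some regional loss stays open, since chromosome 9 as a whole was at 0.755 and no chromosome was below 0.668. The general shortening of the MITF siRNA list could account for the covered length at CD274, at percentile 10.1 of matched windows, although 1 of the 2 control peaks without a counterpart there was strong, in a decile where 7.26% of control peaks lacked one. PDCD1LG2, at the 1.80th percentile, was not low enough to exclude it once the 3 loci named in advance are allowed for. An effect of MITF loss on the PDCD1LG2 side of the locus may be worth a replicated measurement.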
